A study of Arabidopsis thaliana with 4 samples.

How the data were processed

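The series holds 4 Agilent 2-colour arrays of Arabidopsis thaliana. Each compares total RNA from the rosettes of 35S:HaHB1 plants, labelled with Cy5, with that of Col-0 wild type, labelled with Cy3. The labels give 2 transgenic lines with 2 biological replicates each. All 4 arrays have the transgenic sample in Cy5, with no dye swap, so in any comparison against wild type the dye effect of a gene cannot be separated from genotype. It cancels only in the difference between the lines. Each ratio is tested against 0, which leaves out the spread of the wild type itself if its RNA was shared among arrays, and the labels do not say whether it was.

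Per the file headers, the scanner files were made with Agilent Feature Extraction 9.5.3.1, and their mean and background intensity values are scanner brightness before any normalization. Also per the file headers, the deposited log10 ratios are red over green after background subtraction, spatial detrending and dye normalization by that software. The authors' series table of log10 values matched the log ratio column of the scanner files, with a largest difference of 0 and a median of 0 for each array, which settles its scale, centring and direction. The genome build behind the probe coordinates is not given in the sources used here.

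Each file held 39102 spots, of which 37685 were gene spots of 37478 probes. A gene was taken to be a locus, and 26236 probes had one, over 25665 loci. The 11242 probes without a locus stayed out of the main fit, a restriction decided after the files had been opened, and were tested apart. Of the tested loci 23504 were found in the TAIR10.1 gene table, and 9806 have a symbol there. Older names in the scanner files were replaced by those symbols.

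In R 4.3.3 with limma 3.58.1, the mean spot signal was background-corrected by normexp with an offset of 50, and log2 ratios were normalized by loess within each array, with control spots at weight 0. Outlier spots were set to missing, from 12 to 103 per array. A gene was represented by its brightest probe, which mattered for 537 genes with more than 1. A gene was tested where that probe was well above background in at least 1 channel on at least 2 of the 4 arrays and had a value in each line, which left 23680 genes. Signal stood well above background for 65.9% to 90.7% of gene spots in green and 76.7% to 95.8% in red, with the highest shares on line B replicate 1. A gene's dim channel below background on every array of a line gives only a bound, computed per channel after loess and Aquantile normalization and open to dye bias.

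The linear model held a mean for each line, fitted with lmFit and eBayes (prior degrees of freedom 3.73). Contrasts were the mean of both lines, line A, line B and line A minus line B, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the moderated ones of that model, with the spread of each gene estimated over both lines, also for a single line. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 23 lists, and again with an estimated correlation and with fry. With an estimated correlation camera had only the few residual degrees of freedom of the 4 arrays, so it could hardly call any list. Not being called there is no evidence that a list was unshifted. The estimated correlations ran from −0.0991 (stomatal list) to 0.829 (glucosinolate list). Most lay above the preset, which makes the preset test too lenient for such lists. The 23 lists held 389 memberships. Of these 376 matched the symbol and locus in the reference, 2 matched by the start of a reference name, and 11 were kept by locus where the reference gives no symbol. That reading of the mapping rule was made after the files had been opened and before any list value was seen. The list of pathogenesis-related proteins, glucanases and chitinases was chosen knowing that a publication names such genes, and is not independent evidence.

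Groups, designs, lists and most alternatives were fixed before the data were examined, and the fixed fit gives the values reported. For the mean of both lines the naming rule took the 12 largest changes in each direction among passing genes, or, with fewer than 5 passing, the 10 with the smallest p in each direction as values that did not pass. Between lines it took 8, or, with fewer than 3 passing, the 5 with the smallest p. Each list added its 4 members with the largest absolute ratio, and 4 relatives of HaHB1 and 4 pathogenesis-related genes were always named. A few further list members that passed over their list alone are named beside these and were chosen after their values were seen, as were values quoted for line B alone.

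Where 503 genes had at least 2 tested probes, the brightest and the next probe were opposite in sign for 191, and their ratios correlated at 0.501 across genes. Among 26 such genes with an absolute ratio of at least 0.5, 4 were opposite.

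The fits were tested on simulated data drawn with the prior variance and degrees of freedom of the real fit, 10 data sets with 200 changed genes each among 23680 genes, for the mean of both lines over 4 arrays. Changes of 1, 2 and 3 on the log2 scale were recovered for 622 of 670, 670 of 670 and 659 of 660 genes, and 101 of 2053 calls were false. All 200 planted changes were this large, which eases the adjustment over all genes. In the real data 71 genes reached an absolute log2 ratio of 1 and 0 were called. The recovery therefore checks the code and does not give the power of the real fit. A list shifted by 0.3 was called in 10 of 10 data sets, and of 220 tests of other lists 0 were called. Genes were drawn independently of each other there. In the real data the estimated correlation reached 0.573 for cell division and 0.829 for glucosinolate synthesis. The simulated list counts therefore do not give the rate of false list calls in these data. A first version drew its variances from shrunken estimates and was corrected. Agreement between lines was set beside 20 data sets simulated without effect for a shared and for separate wild-type samples. The first version of the shared simulation left too large a spread in the transgenic part and was corrected.

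In all 24 alternatives were tried, of which 4 were added after seeing the data: background from the negative-control spots, array weights, probes without a locus included, and all arrays as a single group with line B replicate 1 left out. The planned ones changed background correction, normalization, filters, treatment of outlier spots and of multiple probes, the model, the set test and the arrays used. Array correlations and a first set of calls had been seen before the tests of technical explanations were written down. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures and mapped the lists.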

Results

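HaHB1 is a homeodomain-leucine zipper transcription factor of subfamily I from sunflower. Arabidopsis thaliana plants of the Col-0 ecotype that carried it under the constitutive 35S promoter were compared with untransformed wild type. The labels give 2 independent transgenic lines, A and B, with 2 biological replicates each. Whole rosettes were taken from plants grown on soil for 21 days under 16 h of light. RNA of each transgenic replicate was labelled with Cy5 and hybridised on a 2-colour Agilent array together with Cy3-labelled wild-type RNA, which made 4 arrays. Ratios are given as log2 of transgenic over wild type. After filtering, 23680 genes were tested, and the number of arrays limits the precision of every value.

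The arrays differed in brightness. The median gene spot reached 1330 units in green and 2295 in red on line B replicate 1, against 133 to 185 in green and 216 to 266 in red on the other arrays. Negative-control spots were also brighter there, with medians of 410 in green and 655 in red, against 52.1 to 53.8 and 67.9 to 68.6 elsewhere. Across genes, the log2 ratios of line A replicates 1 and 2 correlated at 0.519. Line B replicate 2 correlated at 0.459 and 0.407 with the line A replicates, and at 0.172 with line B replicate 1. Genes are not independent replicates, so these correlations only describe the arrays.

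**Figure D1:**
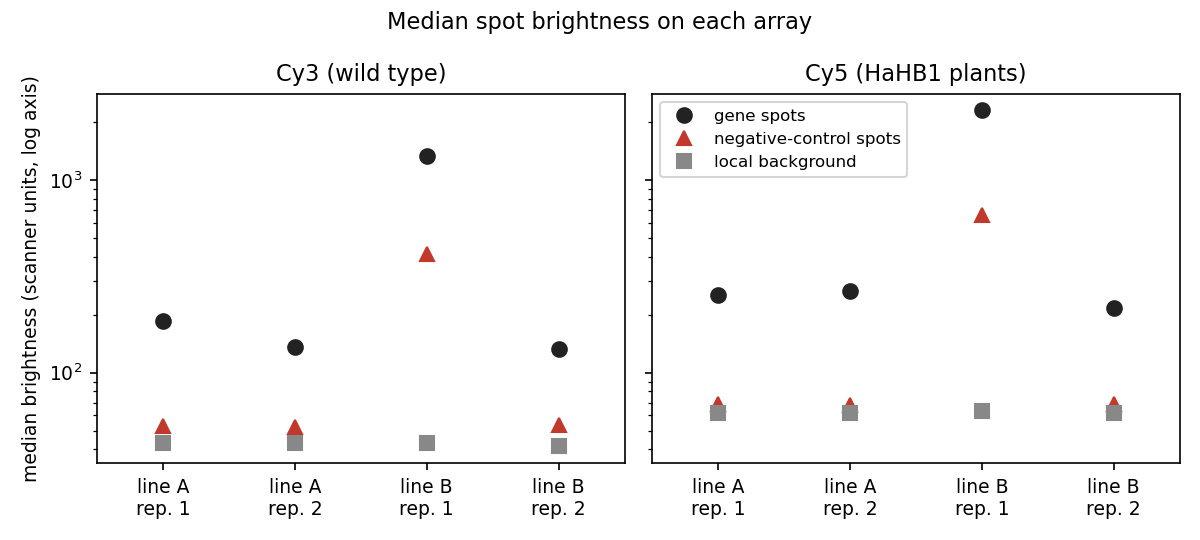
Median brightness (scanner units, log axis) of gene spots, negative-control spots and local background on each of the 4 arrays, for the Cy3 channel (wild type) and the Cy5 channel (HaHB1 plants). Gene spots and negative-control spots of line B replicate 1 sit above those of the other arrays, at 1330 and 410 units in Cy3, while its local background of 43 units does not.

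The first comparison asked which genes differed between HaHB1 plants and wild type over both lines. The lowest mean ratio among the named genes was that of AT3G01345, at −2.47 ± 0.17 (SE, n = 4 arrays), with −1.99 to −2.87 on single arrays. TCH4, a touch-inducible xyloglucan endotransglucosylase, had −1.01 ± 0.08, ANL2, a homeodomain-leucine zipper factor of subfamily IV, −0.93 ± 0.07, and GA2OX2, which inactivates gibberellins, −0.79 ± 0.07. On the high side stood the defensin genes LCR69 (1.22 ± 0.09) and LCR68 (0.75 ± 0.07), PSBR of photosystem II (0.87 ± 0.07) and ARD3, an enzyme of methionine salvage (0.81 ± 0.07). Each of these genes had the same sign on 4 of 4 arrays. None passed limma's test after adjustment over all genes.

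Over the 23680 genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.0569 shared by 16 genes. At an unadjusted p under 0.05 it gave 5472 genes, 2453 above and 3019 below 0, where 1184 are expected by chance. Of 23614 genes with a value on every array, 3275 lay above and 3964 below 0 on all 4, or 30.7%, against 12.5% if the arrays were independent and without effect. Dye effects, or wild-type RNA shared among arrays, would raise both counts too, so neither excess by itself shows an effect of the transgene. At an absolute log2 ratio of at least 1 there were 71 genes.

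AACT1, an acyltransferase that couples hydroxycinnamic acids to agmatine, had the smallest p above 0, with a mean of 1.48 ± 0.09. GRP3S, a glycine-rich protein, had 1.31 ± 0.11, the transporter gene AT1G08230 1.11 ± 0.10, and UGT73B3, a glucosyltransferase, 0.96 ± 0.09. AT1G76590 and AT4G20420 had 1.28 ± 0.12 and 1.14 ± 0.08. Below 0 the rule also named ACBP4, an acyl-CoA-binding protein, at −1.16 ± 0.10, although its ratio was −0.15 and −0.27 in line A against −1.87 and −2.35 in line B. AT5G37960 had −1.32 ± 0.11, AT4G16563 −1.20 ± 0.11, AT5G37940 −1.20 ± 0.09, AT3G05320 −0.88 ± 0.07 and the SAUR-like gene AT4G38860 −0.86 ± 0.08. These 20 genes had adjusted p-values of 0.0569 to 0.0574. The probe of AT3G01345 lies on chromosome 3 at 130402 to 130461, that of AACT1 on chromosome 5 at 24627270 to 24627329 and that of LCR69 on chromosome 2 at 528968 to 529027, in the coordinates of the scanner files, whose build is not given in the sources used here. Whether a probe lies in an exon or an untranslated region was not analysed here.

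**Figure D2:**
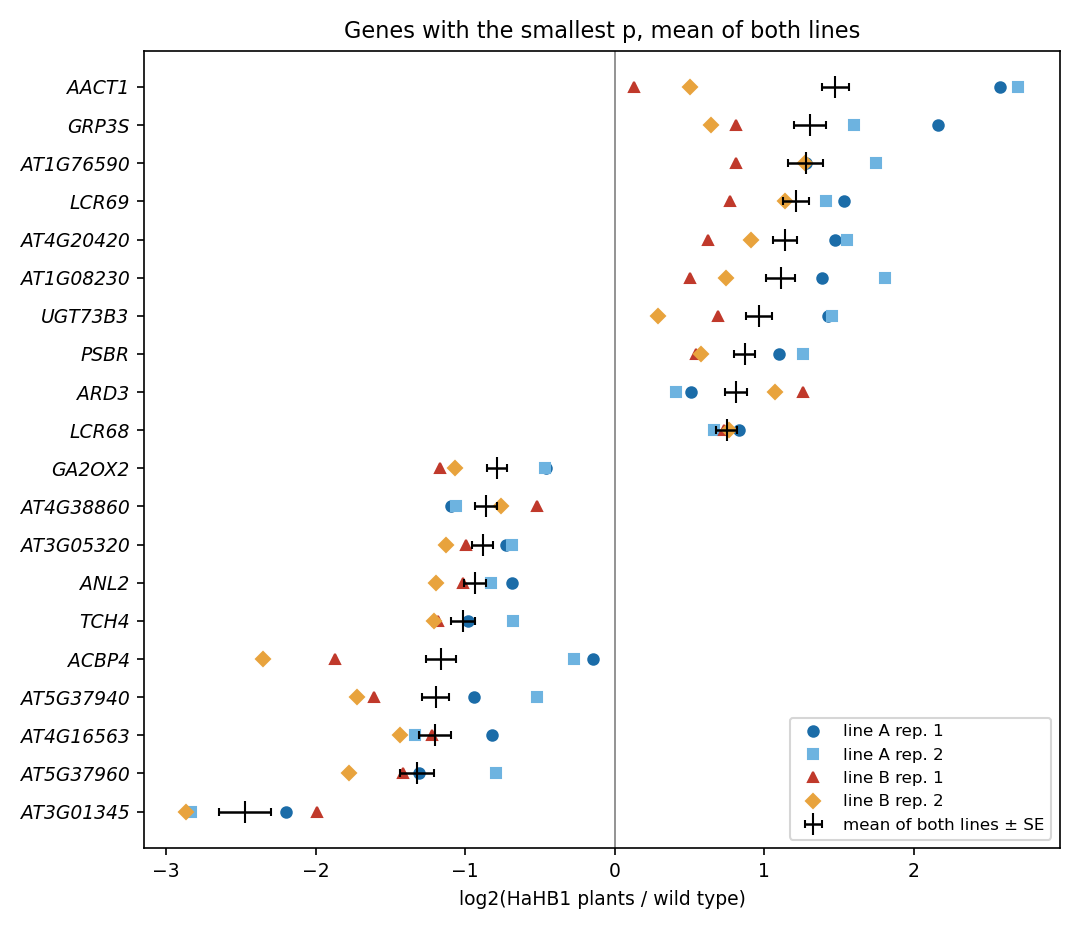
Log2 ratio of HaHB1 plants over wild type for the 10 genes above and the 10 below 0 with the smallest p, one symbol per array, with the mean of both lines and its standard error in black. AACT1 lies at 2.57 and 2.70 in line A and at 0.13 and 0.50 in line B, while AT3G01345 lies at −1.99 or lower on every array.

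The count of 0 depended on the arrays and on the processing. It became 608 genes (334 higher, 274 lower) without line A replicate 1 and 6 without line A replicate 2, and stayed at 0 without either line B array. Median centring in place of loess gave 2370 genes (2042 higher, 328 lower), trend and robust eBayes 137, a stricter filter on dim probes 46, and leaving out line B replicate 1 with the line ignored, a setting chosen after seeing the data, 37.

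Photosynthesis genes lay above other genes. Of 22 tested members, 20 had a mean ratio above 0 and 2 below, with a list median of 0.29. When adjusted over the list alone, 10 passed upward and 1 downward, and over all genes 0 passed. Of all tested genes 23.1% had an unadjusted p under 0.05 for the mean by limma. Members of any list can therefore pass when adjusted over it alone, here and in the lists below. Among those upward were LHCB6 (0.67 ± 0.07) and CAB2 (0.58 ± 0.12), which encode light-harvesting proteins of photosystem II, and PSBO1 (0.63 ± 0.09) of the oxygen-evolving complex. The member that passed downward was CAB1, another light-harvesting gene, at −1.36 ± 0.24. Camera, limma's competitive gene set test, called the photosynthesis list upward with an adjusted p of 2.55e-05 at the preset correlation. It was not called with an estimated correlation (adjusted p = 0.663 with an estimated correlation), nor with Agilent's processed log ratio (adjusted p = 0.0926). The test with an estimated correlation has few degrees of freedom here, so it says little about this list. Over all alternatives the adjusted p of photosynthesis ran from 5.31e-17 to 0.663. The list's median was 0.23 and 0.33 on line A replicates 1 and 2, and 0.11 and 0.39 on line B replicates 1 and 2.

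Defence genes were the second group with high ratios. Of 24 genes of salicylic acid defence, 20 lay above 0 (median 0.25), and 5 passed upward when adjusted over the list alone, 0 over all genes. LURP1 was 2.14-fold higher on average (SE of the log2 ratio 0.17), and WRKY38 had 1.00 ± 0.13, PCC1 0.83 ± 0.11 and the glutaredoxin GRX480 0.82 ± 0.15. Of 19 pathogenesis-related proteins, glucanases and chitinases, 16 lay above 0 (median 0.29), and 6 passed upward over the list alone, 0 over all genes. The list's median was 0.29 and 0.44 on line A replicates 1 and 2 and 0.27 on line B replicate 1, but −0.06 on line B replicate 2. The members that passed included the glucanase AT4G16260 (1.04 ± 0.10), the chitinase CHI (0.81 ± 0.24) and PR4 (0.68 ± 0.15). That list was chosen knowing that a publication on HaHB1 plants names such genes, so its count is not independent evidence. Camera called the salicylic acid list upward (adjusted p = 0.000529) and the pathogenesis-related list upward (adjusted p = 0.000915), both with an adjusted p = 0.663 with an estimated correlation. The salicylic acid median was 0.02 and 0.46 on line A replicates 1 and 2, and 0.46 and 0.06 on line B replicates 1 and 2. Without line B replicate 1, salicylic acid defence had an adjusted p of 0.0837, within a range of 9.99e-10 to 0.663 over its alternatives. The adjusted p of the pathogenesis-related list ran from 9.85e-07 to 0.663, with 0.0592 when the line was ignored and line B replicate 1 left out.

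Among the pathogenesis-related genes fixed for naming, PR1 had 0.31 ± 0.11, PR2 (symbol BGL2) 0.85 ± 0.27 and PR5 0.05 ± 0.24, none past the threshold over all genes. PR2 reached 1.96 on line B replicate 1 and 0.27 to 0.85 on the other arrays. PR5 was positive on 2 of 4 arrays, and its mean was −0.32 without line B replicate 1 and −0.10 without line A replicate 2.

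Glucosinolate synthesis genes also lay above other genes. Of 18 tested, 15 were above 0 (median 0.24), and 5 passed upward and 1 downward when adjusted over the list alone, 0 over all genes. IMS2, an enzyme of methionine chain elongation now named MAM3, had 0.82 ± 0.15, and the cytochromes P450 of the core pathway CYP79B2, CYP79F1 and CYP83B1 had 0.59 ± 0.13, 0.50 ± 0.14 and 0.49 ± 0.15. The second probe of CYP79F1 gave 0.14. The regulator MYB34 was the member that passed downward, at −0.37. Camera gave an adjusted p of 0.00381 for the glucosinolate list, and an adjusted p = 0.663 with an estimated correlation. The call was lost without line A replicate 2 (adjusted p = 0.110) and without line B replicate 2 (adjusted p = 0.0677), in a range of 1.67e-07 to 0.663 over its alternatives. The median was −0.04 and 0.64 on line A replicates 1 and 2, and 0.00142 and 0.24 on line B replicates 1 and 2.

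Growth-related genes lay below other genes, although camera called their lists only at the preset correlation and not with an estimated one, which could hardly call any list here. Of 23 expansins and xyloglucan endotransglucosylases, enzymes and proteins that loosen or remodel the cell wall, 21 had a mean below 0 (median −0.20). Adjusted over the list alone 3 passed downward, 0 over all genes. They were TCH4, XTH15 (−0.49 ± 0.11) and EXPA8 (−0.33), while EXPA1 (−0.54 ± 0.15) and EXPA4 (−0.37 ± 0.12) did not pass. Of 22 genes of auxin response, 19 were below 0 (median −0.18), and 6 passed downward over the list alone, 0 over all genes. The Aux/IAA repressor genes SHY2, IAA2 and IAA6 had −0.75 ± 0.07, −0.64 ± 0.10 and −0.63 ± 0.12, and DFL1, which conjugates auxin to amino acids, had −0.46 ± 0.11. Of 19 genes of cell division, 18 lay below 0 (median −0.15), with CDKB2;2 (−0.49 ± 0.07) and CYCB2;3 (−0.38 ± 0.09) the 2 that passed over the list alone, 0 over all genes. CYCB2;4 had −0.30 ± 0.10 and AUR1 −0.25 ± 0.10. With median centring in place of loess the median of the cell division list was 0.00899 and that of all genes 0.10.

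Camera called the expansin list and the auxin list downward at an adjusted p of 0.000529 each, and the cell division list at 0.000915. All of these 3 lists had an adjusted p = 0.663 with an estimated correlation. Without line A replicate 2, auxin response had an adjusted p of 0.106 and cell division 0.116, and with median centring cell division had 0.106. The ranges over alternatives were 7.72e-07 to 0.663 for expansins and xyloglucan endotransglucosylases, 1.59e-08 to 0.663 for auxin response and 3.91e-06 to 0.663 for cell division. On line A replicates 1 and 2 and line B replicates 1 and 2 the median was −0.12, −0.46, −0.10 and −0.19 for expansins, −0.00356, −0.56, −0.11 and −0.29 for auxin response, and −0.11, −0.38, −0.04 and −0.13 for cell division.

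Genes of cuticular wax and lipid transfer had some of the lowest ratios of any list. CYP96A15, the midchain alkane hydroxylase, had −1.62 ± 0.22, CER4, an alcohol-forming fatty acyl reductase, −1.07 ± 0.11, and the lipid transfer protein genes LTP4 and LTP3 −1.23 ± 0.20 and −1.03 ± 0.16. Of 16 tested, 10 lay below 0, and 7 passed downward and 1, LTP2, upward when adjusted over the list alone, 0 over all genes. Camera called the list downward (adjusted p = 0.0177, and adjusted p = 0.663 with an estimated correlation). The median of the list was −0.13, and with median centring it was 0.0603 while camera still called it downward. Its median was above 0 on line A replicate 1, at 0.0431, and −0.25, −0.29 and −0.21 on line A replicate 2 and line B replicates 1 and 2. The adjusted p of cuticular wax and lipid transfer ran from 1.40e-05 to 0.663 over alternatives, with 0.0781 when the line was ignored and line B replicate 1 left out.

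Lists that mark tissue, stage and handling were read in the same way. Of 16 genes of leaf senescence and dark-induced genes, 12 lay above 0 (median 0.20), and 5 passed upward and 2 downward when adjusted over the list alone, 0 over all genes. The senescence regulator NAP had 0.68 ± 0.20, while SAG12, a cysteine protease used as a senescence marker, had −1.26 ± 0.27. DIN2 (1.04 ± 0.37) and SAG13 (0.74 ± 0.27) did not pass. Of 13 floral and flowering-time markers, 11 lay below 0 (median −0.12, and −0.01 with median centring), and 2 passed downward and 1 upward over the list alone, 0 over all genes. They were FT, which promotes flowering (−0.84 ± 0.08), AGL20, also called SOC1 (−0.30 ± 0.08), and SVP, a floral repressor (0.59 ± 0.10). SEP3 had −0.52 ± 0.20. All 7 trichome regulators lay above 0 (median 0.16), with ETC1 at 0.27 ± 0.08, GL3 at 0.18 ± 0.07, CPC at 0.17 ± 0.07 and GL2 at 0.16 ± 0.10, and 0 passed over the list alone or over all genes.

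Camera gave each of the senescence, floral and trichome lists an adjusted p of 0.0393, and an adjusted p = 0.663 with an estimated correlation. The senescence call was lost without line A replicate 1 (adjusted p = 0.133) and without line B replicate 2 (0.0628). The floral call was lost without line A replicate 1 (adjusted p = 0.162) and without line B replicate 2 (0.430). The trichome call was lost without line A replicate 1 (adjusted p = 0.0904), line A replicate 2 (0.0623) or line B replicate 2 (0.292). Over alternatives the adjusted p ran from 0.00578, 0.00140 and 0.00901 up to 0.663 for these lists in turn, and of 23 alternatives 13, 12 and 13 called them. With Agilent's processed log ratio and with normexp at offset 0 the adjusted p was 0.0974 and 0.0572 for leaf senescence and dark-induced genes, 0.0671 and 0.0534 for floral and flowering-time markers, and 0.104 and 0.0593 for trichome regulators, so that none was called. The floral median was −0.14 and 0.0894 on line A replicates 1 and 2 and −0.05 and −0.52 on line B replicates 1 and 2. In the same order the senescence median was 0.33, 0.32, 0.01 and 0.14 and the trichome median 0.13, 0.31, −0.03 and 0.32.

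**Figure D3:**
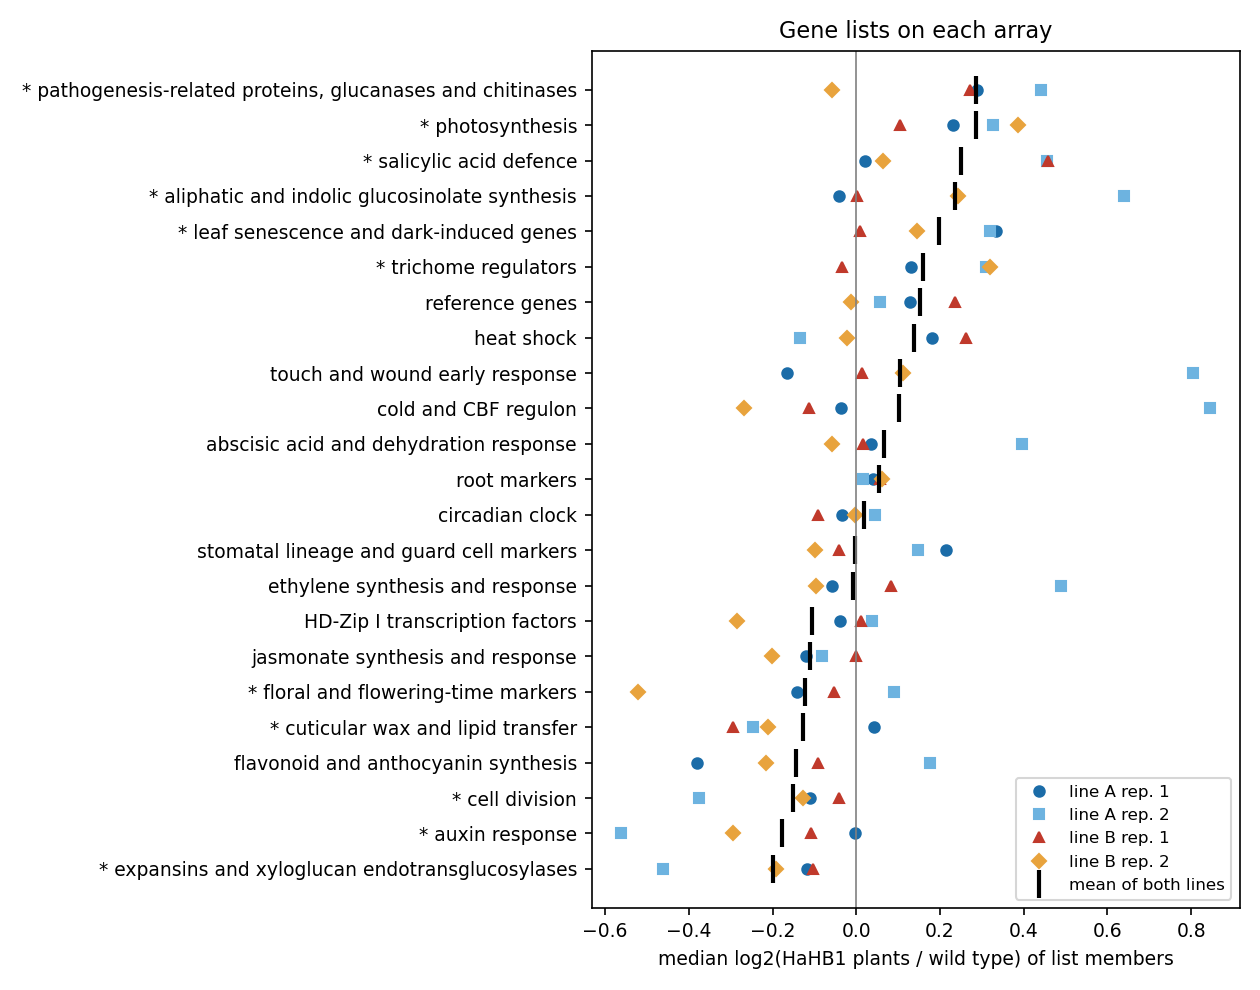
Median log2 ratio of HaHB1 plants over wild type of the members of each of the 23 gene lists, one symbol per array and a black bar for the mean of both lines; an asterisk marks the 11 lists with a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation, which could hardly call any list on so few arrays, and with fry, 0 lists were called. The medians run from −0.20 for the expansin list to 0.29 for the photosynthesis and pathogenesis-related lists.

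The other 12 lists were not called. In jasmonate synthesis and response, 5 of 23 genes passed upward and 6 downward over the list alone, with TIFY7 at 0.58 ± 0.16 and CYP94C1, JMT and AOC2 at −0.75 ± 0.15, −0.73 ± 0.12 and −0.62 ± 0.11 (median −0.11, adjusted p = 0.103, and 0.0379 without line B replicate 1). In the cold and CBF regulon, DREB1A, CBF1 and COR27 were the 3 of 16 that passed, all upward, at 1.23 ± 0.25, 0.67 ± 0.16 and 0.37 ± 0.08, while COR47 had −0.28 ± 0.13. The cold list had a median of 0.10, but −0.12 with scaling between arrays and −0.19 without line A replicate 2 (adjusted p = 0.242, and 0.000200 without line A replicate 1). Of 19 genes of abscisic acid and dehydration response, 3 passed upward and 3 downward, with RD26 at 0.88 ± 0.15, ABF3 at 0.42 ± 0.11, P5CS1 at −0.53 ± 0.08 and LEA7 at −0.46 ± 0.12 (median 0.07, adjusted p = 0.134, and 0.0113 without line A replicate 1). In flavonoid and anthocyanin synthesis LDOX, at −0.61 ± 0.10, was the 1 of 17 that passed, with DFR at −0.59 ± 0.17, TT7 at −0.40 ± 0.10 and the activator PAP1 at 0.57 ± 0.24 (median −0.14, adjusted p = 0.134, and 0.000783 without line A replicate 2, with a median of 0.0361 without line A replicate 1). Across these 12 lists, 0 genes passed over all genes.

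Of 15 homeodomain-leucine zipper genes of subfamily I, the family of HaHB1, 11 lay below 0 and 0 passed over the list alone (median −0.11, and 0.0160 with median centring). HB16 had −0.44 ± 0.12, HB5 −0.35 ± 0.08 and HB-12 0.44 ± 0.18. Camera gave this HD-Zip I list an adjusted p of 0.120, 0.0443 without line A replicate 2 and 0.0173 without line B replicate 1. The closest Arabidopsis relatives of HaHB1 had −0.18 ± 0.08 for ATHB13, 0.01 ± 0.08 for AtHB23 and −0.24 ± 0.07 for HB-3, with ATHB13 at 4.54e-05 under median centring and AtHB23 at −0.0720 with scaling between arrays. ATHB20 was not among the tested genes. The array annotation named 0 probes for HaHB1 itself, so the level of the transgene was not analysed here.

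In the ethylene list (18 tested) ERF104 at 1.08 ± 0.24 passed upward and EBF2 at −0.66 ± 0.11 downward over the list alone, while AT5G51190 and ERF5 had 0.58 ± 0.30 and 0.57 ± 0.29. Its median was −0.00669, its mean 0.10 and its test upward (adjusted p = 0.891, and 0.0316 without line A replicate 1), and the median was 0.23 with median centring. Of the 13 touch and wound early response genes STZ and RHL41 passed upward (1.12 ± 0.26 and 0.62 ± 0.10) and 1 passed downward, while BAP1 and CML37 each had 0.62 ± 0.20 (median 0.10, adjusted p = 0.295, and 6.61e-05 without line A replicate 1). The touch list's median was 0.80 on line A replicate 2 and −0.17 on line A replicate 1, and −0.14 for the mean without line A replicate 2. Among 10 heat shock genes HSP70 (0.50 ± 0.08) passed over the list alone, and HSP90.1, AT1G53540 and AT1G07400 had 0.32 ± 0.10, 0.18 ± 0.10 and 0.17 ± 0.17 (median 0.14, adjusted p = 0.183, 0.0308 without line A replicate 2 and 0.0383 without line B replicate 2).

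No gene of the circadian clock list passed among 20, with CCR1 at −0.80 ± 0.23, GRP7 at −0.24 ± 0.24, GI at −0.23 ± 0.11 and RVE2 at 0.20 ± 0.30 (adjusted p = 0.734). The clock list's median was 0.0180, −0.0162 with Agilent's processed log ratio and −0.00692 with scaling between arrays, its mean was −0.06 and its test pointed down, and GRP7 stood at 0.0574 with median centring. Without line A replicate 1, GRP7 had 0.0699 and RVE2 −0.29. Among 10 root markers, PYK10, PBP1 and BGLU22 had −0.58 ± 0.19, −0.39 ± 0.10 and −0.35 ± 0.12 and SHV2 0.25 ± 0.09, and 0 passed. The root list had a median of 0.0546, −0.0169 with median centring, a mean of −0.06 and an upward test (adjusted p = 0.874). Of 9 stomatal lineage genes TMM passed upward over the list alone (0.40 ± 0.08), while SPCH, KAT1 and MUTE had −0.23 ± 0.09, 0.15 ± 0.08 and 0.14 ± 0.07. The stomatal list had a median of −0.00258 and a mean of 0.06 (adjusted p = 0.295), with a median of 0.18 under median centring. Of 14 reference genes UBQ10 passed upward over the list alone (0.67 ± 0.10), and AT5G60390, TUB2 and YLS8 had 0.40 ± 0.11, 0.37 ± 0.09 and 0.25 ± 0.10 (list median 0.15, adjusted p = 0.0909, 0.0402 without line A replicate 2 and 0.0120 without line B replicate 2).

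In the contrast for line A, AACT1 had a ratio of 2.64 ± 0.12 (n = 2 arrays, spread estimated over both lines), or 6.22-fold. Its adjusted p by limma was 0.0280. It was the 1 gene that limma called in that line, with 0 lower. At an unadjusted p under 0.05 there were 5169 genes, 2474 above and 2695 below 0. AACT1 was not called without line A replicate 2 (adjusted p = 0.0775), without line B replicate 1 (0.0635) or without line B replicate 2 (0.0638), and without line A replicate 1 the count was 384 genes. Nor was it called with no background subtraction (adjusted p = 0.0703), with scaling between arrays, or with Agilent's processed log ratio and the authors' series table (0.0625 in each), where the 1 gene called in line A was AT5G11130 (adjusted p = 0.0270). For AT5G11130 the wild-type signal was not well above background on both line A arrays, so the HaHB1 signal there was at least 2.36-fold higher, with an adjusted p of 0.0647 for line A. The adjusted p of AACT1 ran from 1.43e-37 with median centring to 0.602 with scaling between arrays.

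In the contrast for line B, again with the spread estimated over both lines, 0 genes passed limma's test in either direction, with a smallest adjusted p of 0.172. ACBP4 had −2.11 ± 0.14 (n = 2 arrays), AT5G37940 −1.67 ± 0.13, ANL2 −1.11 ± 0.11 and ARD3 1.17 ± 0.10. At an unadjusted p under 0.05 there were 1881 genes, 743 above and 1138 below 0. The count of called genes rose above 0 without line A replicate 1 and without line A replicate 2. In both cases the spread came from the same 2 line B arrays, so these are not separate checks. With median centring the count was 268.

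The lines were then compared with each other, a contrast in which a constant dye effect of a gene cancels. PDF1.2, a defensin gene induced by jasmonate and ethylene, had 1.23 and 1.78 in line A and −1.50 and −1.15 in line B, a difference of 2.83 ± 0.23. AACT1 differed by 2.32 ± 0.18, ACBP4 by 1.90 ± 0.20 and MYB80, a regulator of the anther tapetum, by 1.37 ± 0.14, each higher in line A. The rule also named AT5G11130, higher in line A, whose difference has no exact size because its wild-type signal in line A was not well above background. Lower in line A than in line B were AT3G19030 (−1.42 ± 0.19), the thionin gene THI2.2 (−1.37 ± 0.21), the ethylene response factor gene RRTF1 (−1.15 ± 0.17) and AT1G59030 (−0.94 ± 0.14). The lectin gene AT5G03350 had 0.17 ± 0.12 in line A against 1.27 ± 0.12 in line B. The mean of PDF1.2 over both lines was 0.09 ± 0.12, but −0.20 with scaling between arrays and −0.0474 without line A replicate 2. Limma called 0 genes between the lines, with a smallest adjusted p of 0.310. At an unadjusted p under 0.05 there were 1395 genes, or 5.89%, where 1184 are expected by chance, and without line A replicate 1 the count of called genes was 41.

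Camera called 9 of 23 lists between the lines at the preset correlation, and 0 with an estimated correlation (each adjusted p = 0.864 with an estimated correlation). The latter test has few degrees of freedom here and says little about these lists. Pathogenesis-related genes were higher in line A than in line B by a median of 0.20, with 4 of 19 members passing for the difference over the list alone, and the cold regulon by 0.56, with 0 of 16. Abscisic acid genes were higher by 0.22 with 3 of 19 passing and floral markers by 0.24 with 2 of 13 passing. Over all genes 0 of these members passed. Without line B replicate 2, the adjusted p was 0.647 for pathogenesis-related genes, 0.358 for abscisic acid genes and 0.985 for floral markers, and without line A replicate 2 it was 0.249 for abscisic acid genes, 0.376 for floral markers and 0.0723 for the cold regulon. For the cold regulon it was 0.0503 without line B replicate 1.

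Genes called in both lines numbered 0, as they had to with 0 called in line B. At an unadjusted p under 0.05, 379 genes lay above 0 in both lines and 568 below, where independent lists of these sizes would share 77.6 and 129.5, and 22 lay in opposite directions. The p-values of both lines use the same spread for a gene, which can also raise the overlap. Across genes the ratios of lines A and B correlated at 0.518, with a covariance of 0.0299. The labels do not say whether wild-type RNA was shared among arrays. In data simulated without any effect, a shared wild-type sample gave a correlation of 0.666 and a covariance of 0.0372, and separate wild-type samples gave values of about 0. The shared wild type was assumed to vary as much as the arrays of a line do. That assumption by itself sets the simulated correlation and share of equal signs. The sign was the same in both lines for 67.5% of genes, against 73.2% simulated with a shared and 50.1% with separate wild-type samples. Shared wild-type RNA may give part or all of the excess, but this simulation cannot say how much.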

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

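The tests of explanations below were fixed before their results were seen, but after the array correlations and a first set of calls. In 9 gene lists the ratios of HaHB1 plants to wild type differed between line A and line B by camera at the preset correlation, and in 0 of them with an estimated correlation (each adjusted p = 0.864 with an estimated correlation), a test with few degrees of freedom here. The median difference, line A minus line B, was 0.56 for the cold and CBF regulon (adjusted p = 0.00268), whose median was 0.85 on line A replicate 2 and −0.04, −0.11 and −0.27 on the other arrays. It was 0.20 for pathogenesis-related proteins, glucanases and chitinases (adjusted p = 0.00686) and 0.22 for abscisic acid and dehydration response (0.0250). Floral and flowering-time markers differed by 0.24, cuticular wax and lipid transfer genes by 0.22 and glucosinolate synthesis genes by 0.17 (each adjusted p = 0.0394). The stomatal lineage list differed by 0.17 (adjusted p = 0.0216), although its mean and median over both lines had different signs. Lower in line A than in line B were cell division genes by −0.11 (adjusted p = 0.0132) and salicylic acid defence genes by −0.12 (0.0435). The salicylic acid difference turned to 0.18 without line A replicate 1, 0.03 without line B replicate 1 and 0.0127 with median centring. Without line A replicate 2 the glucosinolate difference turned to −0.07, and the cell division test turned upward at a median of −0.02. Of these 9 lists, each lost its call without at least 1 of the arrays. The adjusted p was 0.0723 for the cold list without line A replicate 2 and 0.0503 without line B replicate 1. Without line B replicate 2 it was 0.647 for pathogenesis-related genes, 0.358 for abscisic acid genes, 0.985 for floral markers, 0.188 for wax genes, 0.104 for stomatal genes and 0.0509 for cell division genes. Without line A replicate 2 it was 0.249 for abscisic acid genes, 0.376 for floral markers, 0.298 for glucosinolate genes and 0.962 for cell division genes. Without line A replicate 1 it was 0.489 for wax genes, 0.146 for stomatal genes and 0.735 for salicylic acid genes, and without line B replicate 1 it was 0.931 for salicylic acid genes and 0.469 for glucosinolate genes.

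Line B replicate 1 had brighter negative-control spots and the lowest correlations with the other arrays. Raised brightness of spots without target may lie behind this, and would then hurt dim genes most. The correlation of that array with the line A mean, relative to that of line B replicate 2, was 0.555 among the 11807 dimmer genes and 0.621 among the 5904 brightest. The difference of 0.0654 (SD 0.0435 over 200 resamples of genes) lay between the 0.2 that raised brightness was taken to need and the 0.05 that would argue against it, so the question stays open. No biological explanation was tested, since both arrays carry labels of the same line.

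The ratios of both lines agreed beyond independent noise, with a correlation of 0.518 across genes. At an unadjusted p under 0.05 in each line, 947 genes had the same direction and 22 opposite directions. For the mean of both lines 5472 genes had an unadjusted p under 0.05, which a change in a single line can also give. A dye effect of single probes may produce the agreement. Of 136 genes with that p for the mean and a second probe at a separate position, 67.6% (exact 95% interval 59.1 to 75.4) had the same sign there. Of the other genes 56.5% did. That share lay between the bounds set for and against a dye effect, so dye and genotype cannot be told apart for these genes in a design without dye swaps. Wild-type RNA shared among arrays, an effect of HaHB1 in both lines, or a mixture of these also stays open. Turning the sign of single arrays gave 8 choices of the transgenic channel, of which 1, the real one, gave 5472 genes and the highest other, with line B replicate 1 turned, 3418, but 8 choices are too few for a share under 0.05.

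By camera at the preset correlation, photosynthesis genes lay above and auxin response, expansin and cell division genes below other genes, but none of these 4 lists was called with an estimated correlation (each adjusted p = 0.663 with an estimated correlation), and without line A replicate 2 auxin response had an adjusted p of 0.106 and cell division 0.116. The test with an estimated correlation has few degrees of freedom here, so it says little about these lists. A bias that depends on brightness may shift such lists, and among 10000 random lists matched on brightness the photosynthesis median stood at percentile 99.5, auxin response at 0.08, expansins and xyloglucan endotransglucosylases at 0 and cell division at 0.7. All lay outside the central 95%. The random lists drew genes independently, while the estimated correlation was 0.474 for auxin response and 0.573 for cell division, so that range is too narrow for such lists. These 4 lists were also picked after a first set of calls. The percentiles therefore show only that unrelated genes of like brightness rarely had such medians. Matched lists for photosynthesis ran from −0.00 to 0.24 against its 0.29, so brightness may carry part of its shift. Harvest at another time of day was argued against by the clock for the mean over arrays only. There morning-phased genes (CCA1, LHY, PRR9 and RVE8) minus evening-phased genes (TOC1, ELF4, LUX, GI and PRR5) gave 0.00884 ± 0.0697 (SE), where at least 0.5 was taken to be needed. On line A replicate 2, where the growth lists were lowest, it was 0.211, above the bound set for arguing against this explanation. On line A replicate 1 and line B replicates 1 and 2 it was −0.0550, −0.0171 and −0.104. The question stays open for line A replicate 2. A hypothesis of lower growth-related and higher photosynthesis transcripts in HaHB1 plants stays open beside dye effects of single probes and wild-type RNA shared among arrays, which apply to these lists too. Line A replicate 2, lowest for the growth lists, also had the highest medians of the touch (0.80) and cold (0.85) lists. Whether handling of that sample plays a part was not tested. The reference genes, a list not called, had a median of 0.15, as large as the −0.15 of cell division.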

How the results depend on the processing

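The settings with background from negative-control spots, with array weights, with probes without a locus, and with line ignored and line B replicate 1 left out were chosen after seeing the data. For the mean of both lines the count of called genes stayed at 0 with no background subtraction, normexp at offset 0, Agilent's processed log ratio, the authors' series table, no filter on dim probes, outlier spots kept, the mean of all probes, line ignored, negative-control background, array weights and probes without a locus. It moved to 2370 with median centring (2042 higher, 328 lower), 137 with trend and robust eBayes (62 and 75), 46 with the strict filter on dim probes (20 and 26), 37 with line ignored and line B replicate 1 left out (18 and 19) and 1 with scaling between arrays. Median centring gave infinite prior degrees of freedom, so that every gene was given the same spread there, and the median of all genes was 0.10. The other causes were not tested. The 46 genes of the strict filter were all among the 2370, and 45 of them among the 137. The slide was planned as a block, which was not run because the 4 arrays lie on 1 slide with 1 scan. Leaving out an array leaves a line with 1 array, which is assumed to vary like the other line.

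In line A the count was also 1 with Agilent's processed log ratio and the authors' series table, but there the gene was AT5G11130 (adjusted p = 0.0270) and not AACT1 (0.0625). It became 2048 with median centring, 42 with trend and robust eBayes, 12 with the strict filter, 11 with array weights, 2 with normexp at offset 0, and 0 with no background subtraction and with scaling between arrays. In line B the count of 0 became 268 with median centring and 2 with trend and robust eBayes. Between lines the count of 0 became 99 (72 higher in line A, 27 lower) and 2 under the same settings. Genes called in both lines became 152 with median centring. Leaving out each array in turn gave 0 to 608 genes for the mean, 0 to 384 in line A, 0 to 22 in line B, 0 to 41 between lines and 0 to 8 in both lines.

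With the replicate number as a block (replicate block), the mean gave 152 genes (70 higher, 82 lower), line A 12, line B 3 and both lines 2. The deviations of same-numbered replicates correlated at 0.0282 across genes over 2 pairs, and no label ties a number to a shared batch, so the samples share only a number.

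Of 23 lists, 11 were called for the mean and 9 between lines. With an estimated correlation both counts were 0, and with fry they were 0 and 0. An estimated correlation leaves camera few degrees of freedom, so its counts of 0 do not show that no list shifted. Fry's mixed p, which asks whether members change in either direction, called 12 for the mean and 1 between lines. Agilent's processed log ratio and the authors' series table gave 7 and 4 each, and line ignored and line B replicate 1 left out gave 6 for the mean. Between lines, no background subtraction gave 5, the strict filter 5, normexp at offset 0 gave 4 and scaling between arrays 4. Leaving out each array gave 9 to 12 for the mean and 3 to 11 between lines.

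The medians of some lists changed sign or direction, and the causes were not tested. With median centring they were 0.0160 for HD-Zip I transcription factors, 0.23 for ethylene synthesis and response (adjusted p = 0.0347), 0.00899 for cell division, 0.0603 for cuticular wax and lipid transfer, −0.0169 for root markers, 0.18 for stomatal lineage and guard cell markers and 0.0127 for salicylic acid defence between lines. With the strict filter root markers had −0.15. Scaling between arrays gave −0.12 for the cold and CBF regulon, −0.00692 for the circadian clock and 0.0286 for the stomatal list. Agilent's processed log ratio and the series table gave −0.0162 for the circadian clock and 0.00855 for the stomatal list. The stomatal list also had 0.0140 with no background subtraction, 0.00165 with negative-control background and 0.11 with line ignored and line B replicate 1 left out, where ethylene had 0.0295 and the circadian clock −0.0151. Leaving out each array gave ranges of −0.0380 to 0.0514 for ethylene, −0.23 to 0.0361 for flavonoid and anthocyanin synthesis, −0.19 to 0.22 for cold, −0.14 to 0.57 for touch and wound early response, −0.0262 to 0.00960 for the circadian clock and −0.0317 to 0.0630 for the stomatal list. Between lines they were −0.35 to 0.18 for salicylic acid defence, −0.26 to −0.0156 for cell division, where the test turned upward, and −0.0724 to 0.39 for aliphatic and indolic glucosinolate synthesis.

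Of named genes, 16 values in all turned sign, none of them past the threshold. With median centring GRP7 had 0.0574 and ATHB13 4.54e-05, and AtHB23 had −0.00226 with normexp at offset 0. With scaling between arrays PDF1.2 had −0.20 and AtHB23 −0.0720. With line ignored and line B replicate 1 left out AT3G19030 had −0.10, RVE2 −0.0272 and PR5 −0.27. Leaving out each array gave −0.0681 to 0.41 for AT1G07400, −0.55 to 0.0699 for GRP7, −0.29 to 0.69 for RVE2, −0.0474 to 0.23 for PDF1.2, −0.0575 to 0.0716 for AtHB23 and −0.32 to 0.41 for PR5. Another 253 gene values passed the threshold under some setting, and 7, all of AACT1 in line A, no longer passed. AT3G01345 was called lower for the mean in 7 settings. Before background subtraction, gene spots were 2.48 to 3.49 times as bright as negative-control spots in green over the 4 arrays, with 3.24 on line B replicate 1. In red they were 3.16 to 3.91 times as bright, which limits what dim genes show on every array. These raw ratios hide a difference. In green the negative-control median was 410 over a local background of 43 on line B replicate 1. Elsewhere it was 52.1 to 53.8 over 41.5 to 43, so only line B replicate 1 had negative-control spots far above local background.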

Other observations

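The gene classes, the anther list and the genes named in this part were chosen after the main values had been seen. Kinesins, motor proteins of which many act in the spindle and phragmoplast, lay below other genes, with 56 of 69 below 0 and a median of −0.11 (camera adjusted p = 0.000337 over 29 classes made from words in the array's gene descriptions, and adjusted p = 0.808 with an estimated correlation). Auxin-responsive proteins, which overlap the auxin list, had 104 of 140 below 0 and a median of −0.09 (adjusted p = 0.00228, and 0.808 with an estimated correlation). Cytosolic ribosomal proteins had a median of −0.17 in line A and 0.03 in line B (adjusted p = 0.0168 for the mean, and 0.886 with an estimated correlation). Higher than other genes were UDP-glycosyltransferases, with 60 of 94 above 0 and a median of 0.06 (adjusted p = 0.0365, and 0.886 with an estimated correlation), and the family of lipid transfer proteins and protease inhibitors, with 48 of 71 above 0 (adjusted p = 0.00905, and 0.808 with an estimated correlation). The other 24 classes were not called.

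Several members of that family had high ratios in both lines. AT3G07450 had 1.65 and 1.95 in line A and 0.51 and 1.85 in line B, AT3G52130 had 1.51, 1.76, 0.41 and 1.62, and AT5G52160 had 1.35, 1.44, 0.29 and 1.33 in the same order. They were set beside a list of 19 genes of anther tapetum and pollen coat that holds none of these genes, of which 18 were tested. The list was not shifted for the mean (median −0.04, camera p = 0.642, and p = 0.885 with an estimated correlation), with 9 members above and 9 below 0. Between the lines its median difference, line A minus line B, was 0.58 (camera p = 0.0323, and p = 0.530 with an estimated correlation). The list's median was −0.67 on line B replicate 2 alone, against 0.14 on line B replicate 1 and 0.0330 and 0.11 on the line A arrays. ACOS5, LAP5 and AMS, which act in pollen wall formation and tapetum development, had 0.89 ± 0.18, 0.85 ± 0.18 and 0.76 ± 0.12, while the pollen coat genes GRP17, GRP19 and EXL6 had −1.56 ± 0.40, −1.03 ± 0.18 and −1.11 ± 0.19 (SE, n = 4 arrays). These 6 passed when adjusted over the list alone, and 0 passed over all genes. MS2 had −3.15 on line B replicate 2 and −0.15 to 0.41 on the other arrays. The labels describe the plants as vegetative.

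Of 7276 tested probes without a locus limma called 0, with a smallest adjusted p of 0.0843, and 847 (11.6%) had an unadjusted p under 0.05.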
